A study of Rattus norvegicus with 6 samples.

How the data were processed

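Gene expression was measured by RNA sequencing of cecal tissue from rats after 7 days on a diet with casein or chicken protein, with 3 libraries per diet. The labels name the organism as rat, while the design text speaks of mice; the gene identifiers in the files are those of the rat. Total RNA was extracted with a commercial kit and libraries were made by Illumina protocols, per the labels' protocols. The submitters' processing notes list Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1, DESeq2 (version not given in the sources used here) and the rat build rn6. The annotation release, the strand setting of the counting and any read filter are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

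The authors deposited a read count per gene for each library, per the file headers, for 34905 genes (32754 with Ensembl identifiers and 2151 with other identifiers), of which 24012 had a read in at least 1 library. No row named anything other than a gene, and the counts were whole numbers with a different total in each library. The authors also deposited 1 table of the comparison of chicken with casein, which holds symbols and a column per library of log2 expression, whose transformation is not stated. Per the file headers, that table gives a mean normalized signal over the 6 libraries, a log2 fold change with its standard error, a test statistic (a score equal to the fold change over its standard error) and p-values with their adjusted p-values. The mean normalized signal deposited by the authors equals the mean of the deposited counts over DESeq2's size factors (largest relative difference 2.5e-09). Deposited log2 columns were not used for tests. Gene symbols came from the authors' deposited table, which pairs 17221 identifiers with one. Older symbols were looked up in a RefSeq gene table of assembly GRCr8. Its build differs from rn6, so it was used for names alone and no coordinates are given.

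Depth ranged from 15718985 to 23907362 counted reads per library. No molecular identifiers are described, so count limits and intervals cover counting error only. No 2 libraries agreed within sampling noise: chi-square per degree of freedom was between 17.7 and 106 over genes with at least 10 reads in a pair. Levels are CPM with TMM-scaled library sizes, given as mean ± SD of 3 libraries, and log2 fold changes are chicken minus casein with a standard error from edgeR (the absolute fold change over the square root of F).

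The main test was edgeR 4.0.16's quasi-likelihood F test in R 4.3.3 (glmQLFit with robust estimation, TMM factors), after filterByExpr with a minimum count of 10 and a minimum total of 15. This left 16751 genes, 14013 of them with a symbol, and p-values were adjusted by Benjamini-Hochberg over these genes; an adjusted p under 0.05 is a call. All 6 libraries entered the fit with diet as the only term. The common biological coefficient of variation was 0.291. For 35 gene lists of pathways, cell types and tissue quality, fixed before the data were examined, camera of limma 3.58.1 with the preset correlation of 0.01 was run on lists with at least 5 tested members, adjusted over the 35 lists. Of 967 list entries 908 matched by symbol, 11 by an older symbol and 48 did not match. List members called over all genes and adjusted over the list alone are both given. With the correlation estimated per list, 0 of the 35 lists passed (smallest adjusted p 0.596), and 0 passed with fry, which tests whether a list's genes move one way (smallest adjusted p 0.0657), against 17 with the preset correlation (7 up and 10 down).

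Genes named in the text followed a rule fixed before the data were examined. It takes, among genes with a symbol that were called, had at least 1 CPM in the higher group and separated the diets, the 10 largest changes in each direction. It adds, for each list called by camera or holding a called member, up to 4 called members with the smallest p, or the 2 with the smallest p where none was called, and 10 genes named in advance (Muc2, Slc26a3, Slc16a1, Mtor, Slc15a1, Reg3g, Tjp1, Ocln, Acta2 and Mki67). At most 2 identifiers without a symbol are named per direction. These parts name 83 genes, of which 65 were called.

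The alternatives tried were RLE factors, upper-quartile factors and library size alone, DESeq2 1.42.0 and limma-voom, 2 other filters, a fit without robust estimation, the replicate number as a block, other thresholds, leaving out each library in turn, leaving out mitochondrial and immune receptor genes, and for lists the estimated correlation and fry. Added after seeing the data were leaving out casein 1 and chicken 1, scaling to the epithelium list, the smooth muscle score as a covariate, and thinning of reads to the smallest library.

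The tests were run first on simulated data made from the means, dispersions and library sizes of these libraries for the comparison of chicken with casein, over 16751 genes with 200 changed. edgeR recovered 2 of 67 genes changed by 1.5-fold, 10 of 67 changed by 2-fold and 46 of 66 changed by 4-fold, and called 2 unchanged genes. DESeq2 recovered 6, 26 and 58 of them and called 49 unchanged genes, and limma-voom recovered 1, 8 and 41 and called 5 unchanged genes. A list lowered 2-fold in a second simulation was called by camera with the preset correlation, with 0 other lists called, and also passed with an estimated correlation (adjusted p = 0.00155). Genes were drawn independently there, whereas list members co-vary in these libraries. With 200 genes changed, most simulated changes of 2-fold or less were therefore not recovered with 3 libraries per diet. In the real comparison 1063 genes were called, of which 619 changed at least 2-fold, so the shares recovered need not carry over to it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.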

Results

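The data describe gene expression in the cecum, the pouch at the start of the large intestine, of rats fed for 7 days on a diet whose protein was either casein, the main milk protein, or chicken protein. There were 3 RNA sequencing libraries per diet, each made from total RNA of cecal tissue. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these samples. The deposited counts held 21249798, 19242636 and 23907362 reads for casein 1, 2 and 3, and 18333179, 15718985 and 19159069 reads for chicken 1, 2 and 3. At these depths 3 reads in a library, the limit set by a count of 0, correspond to between 0.121 and 0.206 CPM, the unit of reads scaled to a common library total. Reads fell on 21347 ± 207 genes in the casein libraries and on 20602 ± 331 in the chicken libraries (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The 13 protein-coding genes of mitochondrial DNA took 11.4 ± 2.43% of reads on casein and 15.3 ± 2.07% on chicken protein (SD, n = 3; two-sided exact permutation p = 0.2). The 10 most abundant genes took 13.0 ± 2.22% and 17.5 ± 2.01% of reads (two-sided exact permutation p = 0.1). The casein libraries also resembled each other less than the chicken libraries did. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.943, 0.954 and 0.964 for the casein pairs and 0.9696, 0.9734 and 0.9765 for the chicken pairs.

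The comparison asked how the protein source changed gene expression in the large intestine within 7 days. On chicken protein, 22 of 30 tested connective tissue genes and 9 of 29 smooth muscle genes were called lower. Neither list passed with an estimated correlation between genes (adjusted p = 0.596 and 0.646) or with fry (adjusted p = 0.0657 and 0.14). Col1a1, which encodes a chain of type I collagen, went from 1791 ± 385 CPM on casein to 294 ± 66.4 CPM on chicken protein (SD, n = 3), a log2 fold change of -2.61 ± 0.24 (SE; adjusted p = 0.00969). Mat2a, which encodes the enzyme that makes the methyl donor S-adenosylmethionine, went from 572 ± 30.4 to 1131 ± 89.7 CPM (SD, n = 3), a log2 fold change of 0.98 ± 0.14 (SE; adjusted p = 0.0183). Of 16751 genes tested with edgeR's quasi-likelihood test, 1063 passed an adjusted p of 0.05, 351 of them higher and 712 lower on chicken protein. The lower genes changed more, with a median log2 fold change of -1.43 against 0.72 for the higher genes. Changes of at least 2-fold were found for 541 lower and 78 higher genes. In all 1063 genes the 3 libraries of one diet lay on one side of the 3 of the other, as they did in 36.5% of all tested genes, where chance gives 10%.

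The number of calls rested on few libraries. It was 232 without casein 1, 803 without casein 2, 499 without casein 3, 0 without chicken 1, 1 without chicken 2 and 596 without chicken 3. Without chicken 1 and chicken 2, 3417 of 17257 and 3424 of 17273 genes had an unadjusted p under 0.05 in edgeR's test. With no difference a share of 0.05 is expected, but genes co-vary, so the excess is no test of the diets by itself. The share of calls that were lower was 67% with the TMM scaling used here, 90.9% with library size alone (150 higher, 1506 lower; median of all genes -0.19 against -0.02) and 98.7% with libraries scaled to the epithelium list (26 higher, 2044 lower; median of all genes -0.45), a setting chosen after seeing the data.

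**Figure D1:**
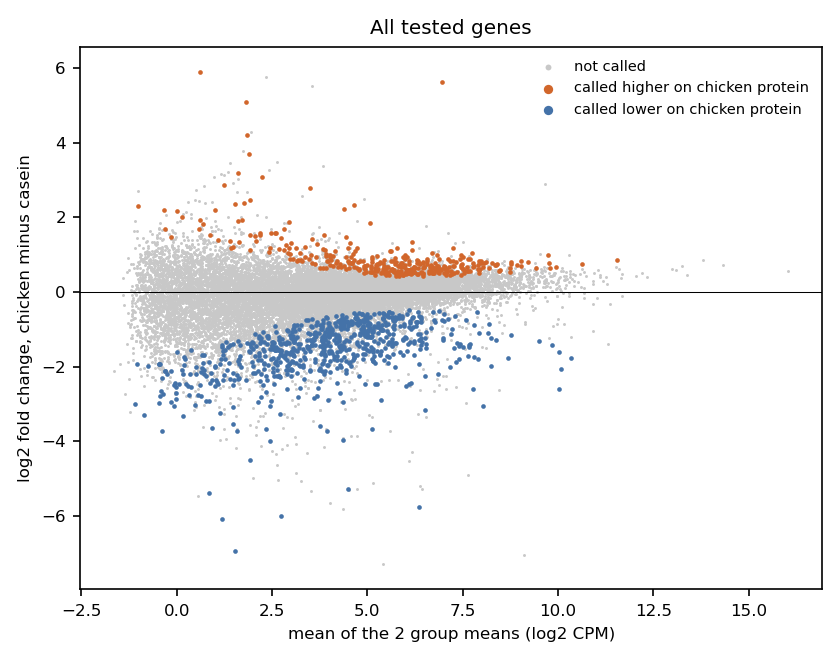
Each point is 1 of the 16751 tested genes, with the mean of the 2 group means on the x axis (log2 CPM) and the log2 fold change of chicken over casein on the y axis. The 712 genes called lower (blue) reach larger changes than most of the 351 called higher (orange), and grey genes passed no threshold.

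Connective tissue was the list with most called members. Of the 30 tested members of the fibroblast and extracellular matrix list, 22 were called lower, 0 higher and 8 were not called. Adjusted over the list alone, 26 were lower. The median log2 fold change was -1.35. Besides Col1a1, these were led by Col3a1 and Col1a2, which encode chains of type III and type I collagen, and Loxl1, a lysyl oxidase that cross-links elastin. Col3a1 fell from 1748 ± 227 to 416 ± 42.1 CPM (SD, n = 3; log2 fold change -2.07 ± 0.17, SE; adjusted p = 0.00858), Col1a2 by 3.06 ± 0.28 and Loxl1 by 1.90 ± 0.16 on the log2 scale. The list mean, as mean log2 CPM of its members, was 6.58 ± 0.29 on casein and 5.20 ± 0.19 on chicken protein (SD, n = 3), with the diets separated. The competitive list test (camera) gave an adjusted p = 1.16e-32 with its preset correlation, and adjusted p = 0.596 with an estimated correlation. Without casein 1, 12 members passed over all genes. No member passed when chicken 1 or chicken 2 was left out, where the list medians were -1.34 and -1.32.

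All 29 members of the smooth muscle list had a negative log2 fold change (median -1.22). Of these, 9 were called lower over all genes, 20 were not called, and 27 were lower when adjusted over the list alone. The number called over all genes was 2, 6 and 3 without casein 1, 2 and 3, and 0, 0 and 20 without chicken 1, 2 and 3. In these fits the list median ran from -1 (without casein 1) to -1.57 (without chicken 3), and camera with its preset correlation called the list in each. Such calls do not by themselves set the diets apart, because camera with this setting also called 11 to 20 lists in splits that mixed the diets. Actg2, the gamma actin of visceral smooth muscle, fell from 2006 ± 87.8 to 592 ± 213 CPM, and Acta2, the alpha actin of smooth muscle, from 1576 ± 266 to 518 ± 238 CPM (SD, n = 3; edgeR adjusted p = 0.0211 and 0.0377). Jph2, which couples the plasma membrane to the calcium store, fell by 2.24 ± 0.30 on the log2 scale, Myocd, a coactivator of smooth muscle genes, by 2.68 ± 0.43 and Hspb6, a small heat shock protein of muscle, by 1.27 ± 0.22. Actg2 and Acta2 are close paralogs, and how the authors' counting split shared reads is not given in the sources used here. Camera's adjusted p was 3.24e-20, and adjusted p = 0.646 with an estimated correlation. The enteric neuron and glia list, whose cells lie partly within the muscle wall, had a median of -0.78 with 0 of 25 members called. Its members with the smallest p were Ret, a receptor of enteric neurons (-1.57 ± 0.39; adjusted p = 0.0558), and S100b, a glial protein (-1.98 ± 0.61; adjusted p = 0.0969). Camera's adjusted p = 0.00762 became adjusted p = 0.735 with an estimated correlation. Without casein 1 the median was -0.44 and the list was no longer called (camera adjusted p = 0.138), and without chicken 3 the median was -1.21.

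Of 19 endothelium and lymphatic members 5 were called lower and 0 higher (8 lower adjusted over the list alone; median -0.52; camera adjusted p = 0.000418, and adjusted p = 0.646 with an estimated correlation). Lyve1, a marker of lymphatic endothelium, fell from 17.1 ± 3.99 to 6.39 ± 0.939 CPM (SD, n = 3), and Cdh5, the cadherin of endothelial junctions, from 32.6 ± 9.01 to 13.2 ± 2.11 CPM. Pdpn, another lymphatic marker, fell by 0.95 ± 0.18 and Vwf, von Willebrand factor, by 0.91 ± 0.17 on the log2 scale. The adipocyte list had the median -2.87, and -1.40 without casein 1. Here 2 of 15 members were called lower and 9 adjusted over the list alone (camera adjusted p = 0.000301, and adjusted p = 0.646 with an estimated correlation). Adipoq, the fat cell hormone adiponectin, stood at 355, 60.5 and 63.7 CPM in casein 1, 2 and 3 and at 5.25, 1.58 and 1.95 CPM in chicken 1, 2 and 3 (log2 fold change -5.75 ± 1.06, SE; adjusted p = 0.0437). Lpl, lipoprotein lipase, had 318, 70.6 and 108 CPM against 12.7, 21.2 and 21.8 CPM. Fat transcripts therefore differed several-fold among the casein libraries too.

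**Figure D2:**
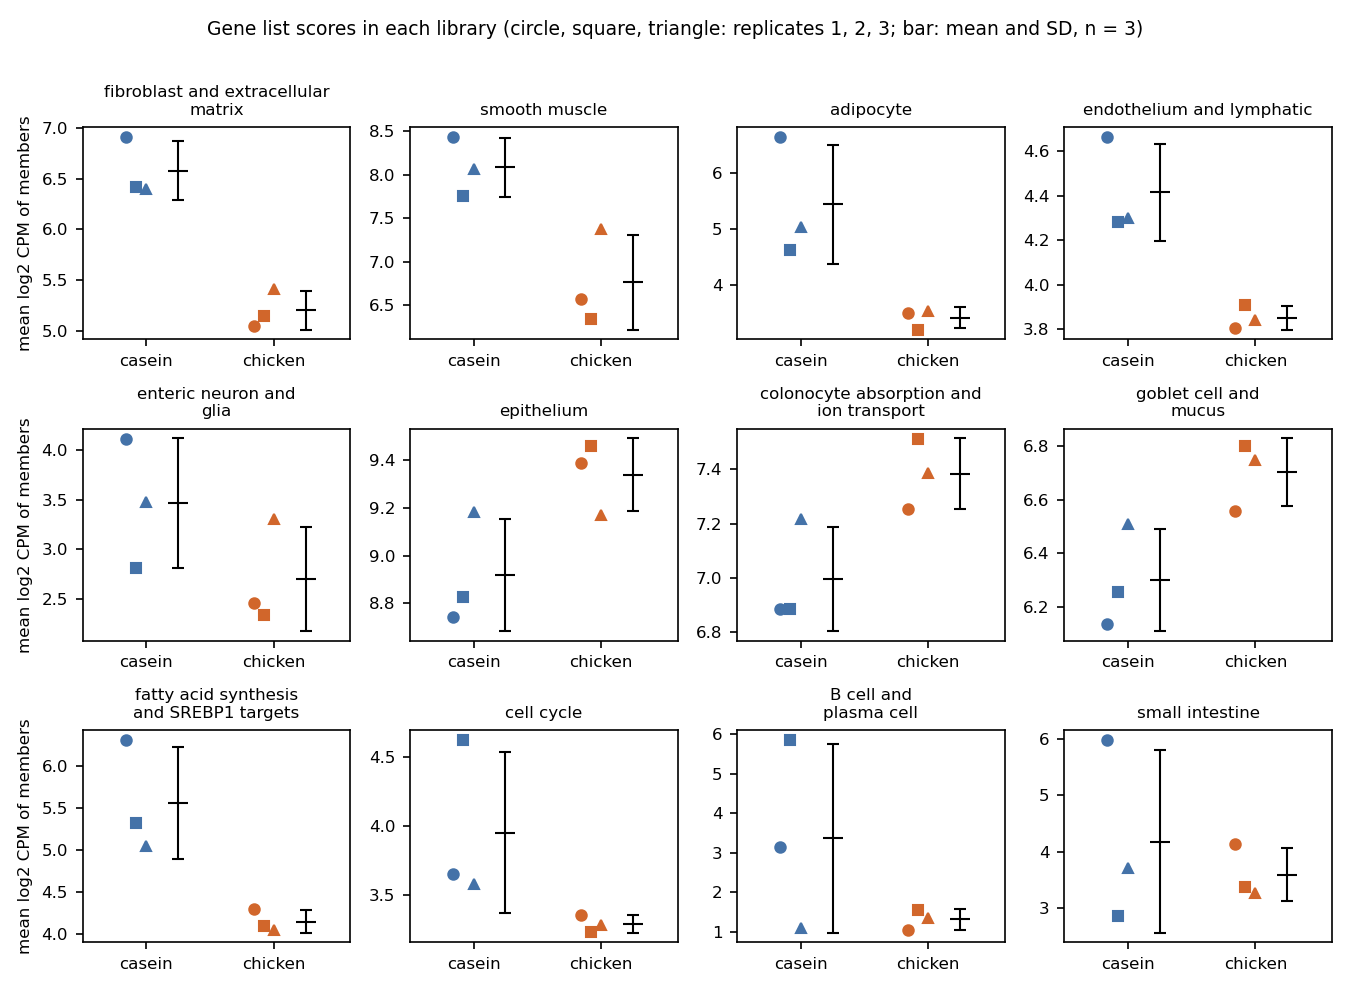
Each panel gives, for 1 gene list, the mean log2 CPM of its tested members in every library (y axis, its range differs between panels) by diet (x axis), with the mean and SD of the 3 libraries as a bar. The fibroblast scores lie at 6.40 or above on casein and at 5.41 or below on chicken protein, while the B cell score is high in casein 2 (5.86) and the small-intestine score in casein 1 (5.98).

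The epithelium list was higher on chicken protein by a smaller amount, and its scores overlapped between the diets, with 9.18 in casein 3 and 9.17 in chicken 3 (two-sided exact permutation p = 0.2). It had a median log2 fold change of 0.43, with 22 of 23 members above 0. Of them 0 were called over all genes and 6 were higher adjusted over the list alone (camera adjusted p = 3.67e-06, and adjusted p = 0.646 with an estimated correlation). Cdx2, the transcription factor of intestinal identity, had 290 ± 67.0 and 481 ± 81.4 CPM (SD, n = 3; adjusted p = 0.0699), and Cdh1, E-cadherin, 1033 ± 125 and 1520 ± 57.5 CPM (adjusted p = 0.0642). Of the 29 members of the list for absorption and ion transport by colonocytes, 4 were called higher and 0 lower over all genes, and 4 were higher adjusted over the list alone (median 0.43; camera adjusted p = 0.000118, and adjusted p = 0.646 with an estimated correlation). Without casein 2 the list median was 0.26, and with the epithelium scaling, chosen after seeing the data, it was 0.03. That scaling sets the epithelium list near 0, and the colonocyte list shares Slc26a3, Car1 and Krt20 with it. The called members were Car2 and Car4, carbonic anhydrases that supply bicarbonate and protons for ion exchange, Scnn1a, a subunit of the epithelial sodium channel, and Aqp8, a water channel. Car2 rose from 1181 ± 159 to 1999 ± 229 CPM, Car4 from 399 ± 37.0 to 649 ± 50.3 CPM, Scnn1a from 97.4 ± 17.4 to 180 ± 38.8 CPM and Aqp8 from 41.0 ± 12.2 to 103 ± 29.0 CPM (SD, n = 3). Scaled to library size alone, the medians of the epithelium and colonocyte lists were 0.27 and 0.26, and Scnn1a, Aqp8 and Car2 no longer passed (log2 fold changes 0.71, 1.16 and 0.60). Slc26a3, the chloride and bicarbonate exchanger of the surface colonocyte, stood at 759 ± 158 and 1032 ± 174 CPM and did not pass (adjusted p = 0.191).

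The goblet cell and mucus list had a median of 0.37, and 0.20 with library size alone, with 20 of 21 members above 0. Spink4, a protease inhibitor made by goblet cells, was the 1 member called, at 183 ± 30.2 CPM on casein and 325 ± 58.1 CPM on chicken protein (SD, n = 3; log2 fold change 0.83 ± 0.18, SE; adjusted p = 0.0442). It was also the 1 that passed adjusted over the list alone (camera adjusted p = 0.000199, and adjusted p = 0.646 with an estimated correlation). Muc2, the main secreted mucin, was fixed in advance as a gene to report, but its symbol matched no row of the authors' deposited table and it was not analysed here. The junction proteins showed no call in the epithelial direction. Tjp1 had 126 ± 11.6 and 128 ± 7.05 CPM and Ocln, occludin, 111.9 ± 11.03 and 126 ± 18.8 CPM (SD, n = 3; adjusted p = 0.886 and 0.450). The sign of the Tjp1 change turned with library size alone (-0.14), with the epithelium scaling (-0.39) and without casein 2 (-0.05), and that of Ocln with the epithelium scaling (-0.24). The tight and adherens junction list was not called (median 0.26, mean 0.09; camera adjusted p = 0.069). Its 1 called member, Jam2, an adhesion molecule of vessels, fell by 0.78 ± 0.17, and 2 members were lower adjusted over the list alone.

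In the list of fatty acid synthesis and SREBP1 targets, 6 of 18 members were called lower and 0 higher (11 lower and 1 higher adjusted over the list alone; median -1.21; camera adjusted p = 5.51e-06, and adjusted p = 0.646 with an estimated correlation). Fads2 and Fads1, the desaturases that make long polyunsaturated fatty acids, fell from 12.7 ± 1.28 to 3.49 ± 0.238 CPM and from 25.6 ± 5.47 to 11.6 ± 0.878 CPM (SD, n = 3). Elovl5, an elongase of the same pathway, fell by 1.71 ± 0.23 and Lpin1, which acts in triglyceride synthesis, by 1.56 ± 0.30 on the log2 scale. The score of this list was highest in casein 1 (6.32, against 5.33 and 5.05 in casein 2 and 3), the library with most fat transcripts. Of the members named here, Fads1 and Lpin1 were also highest in casein 1 (31.6 and 32.1 CPM). Fads2 and Elovl5 were highest in casein 2 (14.1 and 27.8 CPM, against 12.3 and 23.6 CPM in casein 1). In the list of fatty acid oxidation and PPAR targets the 1 called member was Cd36, a fatty acid transporter also found in fat and vessels, which fell from 14.7 ± 2.39 to 3.25 ± 0.583 CPM (SD, n = 3). It was also the 1 lower adjusted over the list alone. This list was not called (median 0.18; camera adjusted p = 0.0529). The sterol synthesis list had a median of 0.18 with 0 of 26 members called (0 adjusted over the list alone; camera adjusted p = 0.0312, and adjusted p = 0.646 with an estimated correlation). Camera no longer called it without casein 3 (median 0.08; adjusted p = 0.141), without chicken 1 (adjusted p = 0.0555) or with library size alone (median 0.01; adjusted p = 0.0595). Its members with the smallest p were Pmvk and Fdft1, enzymes of the mevalonate and squalene steps, with 37.6 ± 0.785 and 54.1 ± 7.29 CPM and with 83.7 ± 9.99 and 118 ± 11.5 CPM (SD, n = 3; adjusted p = 0.0514 and 0.0653).

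Of 29 amino acid and peptide transporters 1 was called, Slc1a5, a glutamine carrier, at 72.6, 60.5 and 29.6 CPM in casein 1, 2 and 3 and 14.7, 17.1 and 14.8 CPM in chicken 1, 2 and 3 (log2 fold change -1.80 ± 0.32, SE; adjusted p = 0.0303). The list had a median of -0.64, with 2 lower adjusted over the list alone (camera adjusted p = 0.00578, and adjusted p = 0.646 with an estimated correlation). The peptide transporter Slc15a1 did not pass (-3.91 ± 2.44; adjusted p = 0.334). It had 113 CPM in casein 1 and 7.06 CPM in chicken 1, and at most 2.58 CPM in the other libraries. Without casein 1 its log2 fold change was 0.90. The scores of the mTOR and amino acid sensing list separated the diets, at 5.21 ± 0.02 on casein and 5.02 ± 0.03 on chicken protein (SD, n = 3; two-sided exact permutation p = 0.1; fry adjusted p = 0.0657). Of its 38 members 4 were called lower and 0 higher (5 lower and 2 higher adjusted over the list alone), while the list was not called (median -0.10; camera adjusted p = 0.347). These were Irs1, an adaptor of the insulin receptor, which fell from 6.49 ± 1.30 to 1.45 ± 0.182 CPM (SD, n = 3), Deptor, an mTOR inhibitor (-0.90 ± 0.18), Pik3r1, a subunit of PI3-kinase (-0.64 ± 0.14), and Eif4ebp1, a translation repressor that mTOR inactivates (-0.89 ± 0.20). Mtor itself had 44.9 ± 1.81 and 35.3 ± 3.04 CPM (SD, n = 3; adjusted p = 0.0957), and passed with library size alone (-0.52). Phgdh, the entry enzyme of serine synthesis, was the 1 called member of 27 in the ATF4 amino acid response list and fell by 1.96 ± 0.37 (list median -0.43; 4 lower adjusted over the list alone; camera adjusted p = 0.0773).

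The list of sulphide and sulphur amino acid metabolism had members called in both directions. Mat2a and Tstd1, a thiosulphate sulphurtransferase, rose, and Cdo1, which oxidises cysteine, fell. Adjusted over the list alone, 4 were higher and 2 lower of 20. Tstd1 had 147 ± 18.7 and 224 ± 21.8 CPM (SD, n = 3). Cdo1 had 61.5, 12.2 and 11.8 CPM in the casein libraries and 2.99, 1.65 and 1.84 CPM in the chicken libraries, highest in casein 1 as the fat transcripts were. The median of the list was 0.31 and camera's direction was up (adjusted p = 0.0312, and adjusted p = 0.646 with an estimated correlation), but the mean was -0.10. This call was lost with the replicate number as a block (adjusted p = 0.13), with library size alone (adjusted p = 0.0514; median 0.14) and without casein 1, casein 2 or chicken 2 (adjusted p = 0.108, 0.118 and 0.0734). For sensing of short-chain fatty acids and oxidation of butyrate, 0 of 21 members were called (1 higher and 1 lower adjusted over the list alone; median 0.29; camera adjusted p = 0.0347, and adjusted p = 0.666 with an estimated correlation). It was not called without casein 1, casein 2 or chicken 2 (camera adjusted p = 0.138, 0.0711 and 0.111). Oxct1, which uses ketone bodies, had 48.0 ± 15.6 and 23.1 ± 3.93 CPM, Echs1, of fatty acid oxidation, 0.799 ± 0.215 and 2.29 ± 0.527 CPM and Slc16a1, a carrier of butyrate, 257 ± 50.3 and 314 ± 37.7 CPM (SD, n = 3; adjusted p = 0.0505, 0.0511 and 0.306). In the oxidative phosphorylation list 2 of 35 members were called higher and 0 lower (7 higher adjusted over the list alone; median 0.23; camera adjusted p = 0.000418, and adjusted p = 0.728 with an estimated correlation). Cox7a2, a subunit of cytochrome c oxidase, rose from 44.1 ± 6.49 to 76.1 ± 8.04 CPM and Ndufa2, of complex I, from 35.3 ± 2.06 to 51.4 ± 5.83 CPM (SD, n = 3). The oxidative phosphorylation list was not called without both casein 1 and chicken 1 (camera adjusted p = 0.0714; median 0.10) or with the epithelium scaling (camera adjusted p = 0.154), settings chosen after seeing the data. With library size alone the medians of the oxidative phosphorylation and short-chain fatty acid lists were 0.06 and 0.12. Under the epithelium scaling the medians of the oxidative phosphorylation, sterol, sulphide, short-chain fatty acid and goblet lists lay below 0.

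The B cell and plasma cell list followed single libraries. It had a median of -3.55 (camera adjusted p = 0.0102, and adjusted p = 0.728 with an estimated correlation), but its score was 5.86 in casein 2, 3.15 in casein 1 and 1.09 in casein 3, which lay among the chicken libraries (1.03, 1.55 and 1.35). Camera no longer called it without casein 2 (median -1.46; adjusted p = 0.118), without chicken 3 (adjusted p = 0.0672), with library size alone (adjusted p = 0.0595) or with a filter of 1 CPM in 3 libraries (adjusted p = 0.0535). The 1 member called of 20, over all genes and over the list alone, was Irf4, a transcription factor of plasma cells and other immune cells, at 11.9 ± 5.70 and 1.21 ± 0.641 CPM (SD, n = 3). In the list of macrophages, dendritic cells and neutrophils 3 of 25 members were called lower and 0 higher, and 3 were lower adjusted over the list alone (median -0.22; camera adjusted p = 0.046, and adjusted p = 0.728 with an estimated correlation). Its scores separated the diets, but camera no longer called it without casein 2, casein 3 or chicken 3 (adjusted p = 0.147, 0.111 and 0.377; medians -0.07, -0.28 and -0.09) or with library size alone (adjusted p = 0.0595; median -0.38). The median was -0.33 without chicken 2. The called members were Mpo, the neutrophil myeloperoxidase (13.1 ± 15.4 and 0.192 ± 0.137 CPM), and Siglec1 and Cd163, receptors of tissue macrophages (-1.68 ± 0.37 and -1.05 ± 0.24). The cell cycle list had a median of -0.76 with all 32 members below 0 and 0 called (0 adjusted over the list alone; camera adjusted p = 0.000118, and adjusted p = 0.728 with an estimated correlation). Its score was highest in casein 2 (4.62, against 3.66 and 3.58 in casein 1 and 3), without which the median was -0.32. Its members with the smallest p were Cdc20 and Rrm2, at 19.2 ± 9.37 and 7.79 ± 1.12 CPM and at 9.91 ± 5.55 and 3.62 ± 0.872 CPM (SD, n = 3; adjusted p = 0.060 and 0.0756). The proliferation marker Mki67 had 39.8 ± 22.7 and 23.5 ± 2.89 CPM (adjusted p = 0.221). No member was called over all genes or adjusted over the list alone, and camera did not call the list, for T and NK cells (median -0.77), MHC class II presentation (-0.66), the interferon response (0.08), innate inflammatory signalling (0.00), mast cells and eosinophils (0.33), antimicrobial and epithelial defence (-0.18), intestinal stem cells (-0.09), the unfolded protein response (-0.04), blood (0.13) and the small intestine (-0.73). Of these, camera's direction was up for antimicrobial defence and the unfolded protein response, whose medians and means lay below 0, and for innate signalling, whose mean was -0.17. The antimicrobial lectin Reg3g had 485, 0.247 and 2.86 CPM in casein 1, 2 and 3 and 12.8, 0 and 0.334 CPM in chicken 1, 2 and 3 (-5.19 ± 2.95, SE; adjusted p = 0.295). Without casein 1 its log2 fold change was 1.49. Reg3g has close paralogs, and how shared reads were counted is not given in the sources used here.

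The remaining lists were not called by camera but held called members. The receptor Nr1i2, which senses bile acids and foreign compounds, rose from 168 ± 11.4 to 269 ± 26.0 CPM (SD, n = 3; log2 fold change 0.68 ± 0.13, SE; adjusted p = 0.0310). It was the 1 call of 33 in the list of AHR and xenobiotic metabolism. There 7 were higher and 3 lower adjusted over the list alone (median 0.14, mean -0.11; camera adjusted p = 0.133). Hlf and Rora, transcription factors of the clock's output and of its loop, fell by 3.02 ± 0.46 and 1.92 ± 0.44 in the circadian list (2 of 18 called, 3 lower adjusted over the list alone; median -0.08; camera adjusted p = 0.770). Both were rare, with 2.49 ± 0.764 and 1.16 ± 0.353 CPM on casein (SD, n = 3). Cpe, a carboxypeptidase that processes hormones in endocrine cells and neurons, fell by 1.23 ± 0.22 as the 1 call of 25 enteroendocrine and tuft cell genes (1 higher and 1 lower adjusted over the list alone; median 0.24; camera adjusted p = 0.121). Among immediate early and heat shock genes, included as a sign of tissue handling, Hspb1 and Fosl1 fell by 1.28 ± 0.25 and 1.40 ± 0.32. The scores of this list separated the diets, at 5.65 ± 0.12 on casein and 5.45 ± 0.06 on chicken protein (SD, n = 3; two-sided exact permutation p = 0.1). The list had a median of 0.01 and a mean of -0.28, with camera's direction down (2 of 26 called, 2 lower adjusted over the list alone; camera adjusted p = 0.915).

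**Figure D3:**
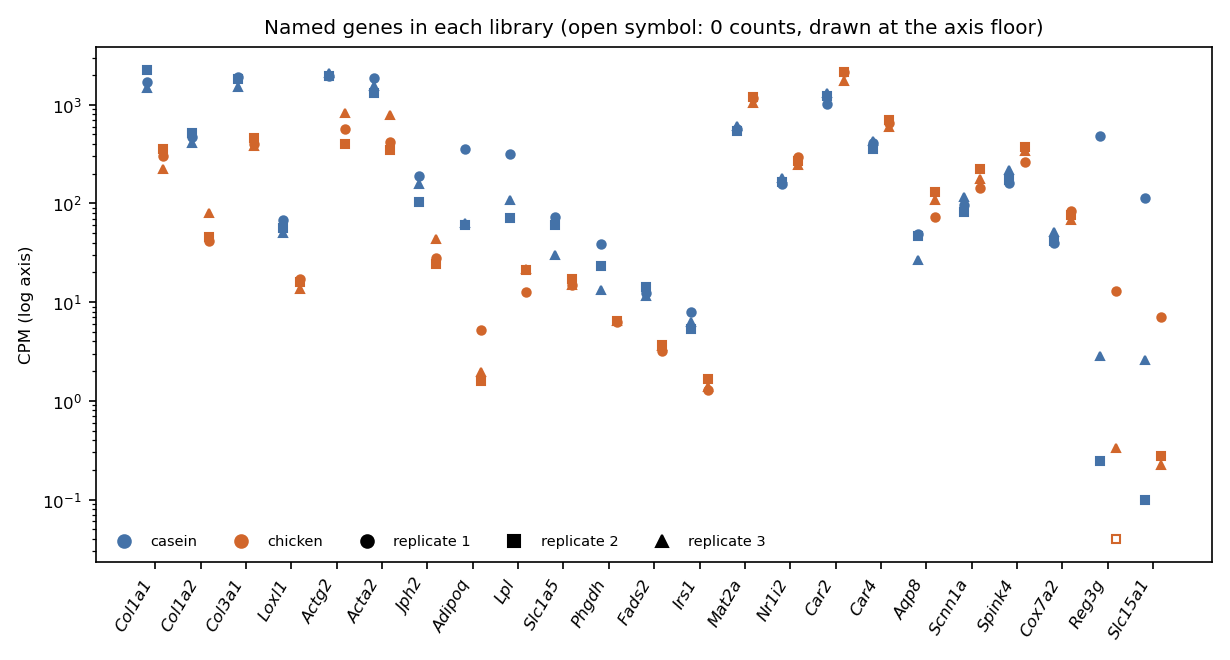
CPM of 23 named genes (log y axis) in each library, blue for casein and orange for chicken protein, with symbol shapes for replicates 1, 2 and 3. Collagen, actin and fat genes lie lower and Mat2a, Nr1i2, Car2 and Car4 higher in all 3 chicken libraries, while Reg3g and Slc15a1 are high in casein 1 (485 and 113 CPM).

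Among called genes with a symbol and at least 1 CPM in the higher group, the 10 largest increases were in Rpph1, LOC100911130, LOC100911727, Miip, Lcn5, LOC103690317, LOC100362684, Pde4c, Cd151 and Kcnk6. Rpph1, the RNA component of ribonuclease P, had 154 reads in the chicken libraries and 3 in the casein libraries, a ratio of 69.6 with an exact 95% interval of 23.4 to 341 that covers counting error only. Lcn5, a lipocalin, rose from 2.85 ± 1.29 to 19.6 ± 12.2 CPM and Cd151, a tetraspanin, from 7.42 ± 1.38 to 34.7 ± 16.5 CPM (SD, n = 3). Pde4c, a phosphodiesterase that degrades cyclic AMP, rose by 2.35 ± 0.42 on the log2 scale. The 4 genes with LOC symbols can share reads with related copies, so their values are uncertain. Among called genes under the same limits, the 10 largest decreases were in LOC691485, Mpo, Adipoq, RGD1563231, C4b, Slc7a10, Slc1a3, Trarg1, Mreg and Pappa2. LOC691485 had 309 reads in the casein and 3 in the chicken libraries, a ratio of 76.0 (exact 95% interval 25.8 to 370). C4b, complement component 4, fell from 44.0 ± 21.9 to 1.14 ± 0.413 CPM (log2 fold change -5.28 ± 0.50, SE; adjusted p = 0.0122). Slc1a3, a glutamate transporter, fell by 3.98 ± 0.55, and Trarg1, a protein of fat cells, had 82.3, 15.2 and 17.5 CPM in casein 1, 2 and 3. Of the 351 higher genes, 62 had no symbol in the authors' deposited table (17.7%), against 48 of the 712 lower genes (6.74%). Novel00623, a locus the authors' file gives without a symbol, rose from 4.94 ± 3.37 to 246 ± 100.3 CPM, and Novel00395 fell from 1.70 ± 0.664 to 0.195 ± 0.121 CPM (SD, n = 3).

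The authors' deposited table compared the same libraries with DESeq2 and called 2865 genes, 1055 higher and 1810 lower on chicken protein, of 17834 with an adjusted p. edgeR called 1060 of these, or 37% of them, all in the same direction, and these were 99.7% of edgeR's own calls. DESeq2 run again on the deposited counts called 2865 genes, and all 2865 were those of the authors' deposited table. Across genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and of edgeR had a Pearson's r of 0.9999.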

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

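Changed with the processing, the 1063 calls (351 higher, 712 lower) stayed within 1.5 times under RLE and upper-quartile factors, both other filters, the fit without robust estimation, limma-voom and the removal of mitochondrial and immune receptor genes, and, chosen after seeing the data, with reads thinned to the smallest library (949 calls). Other settings moved them. The numbers were 1656 (150 higher, 1506 lower) with library size alone, 2865 (1055, 1810) with DESeq2, 2946 (1197, 1749) at an adjusted p under 0.1, and 619, of which 78 higher, with a 2-fold minimum. The other thresholds were applied to the same fit, so there the cutoff alone changed the number. With library size alone the whole distribution shifts. For DESeq2 the cause was not tested in these data. In the simulation it recovered more changed genes than edgeR and called more unchanged ones (49 against 2). Leaving out 1 library gave 0 to 803 calls, 0 to 149 higher and 0 to 654 lower, with fewer samples in each fit, and 14 to 21 lists. Of the settings chosen after seeing the data, 5 genes were called (1 higher, 4 lower) without casein 1 and chicken 1, where 2788 had an unadjusted p under 0.05, 2070 (26 higher, 2044 lower) with the epithelium scaling, and 0 (0 higher, 0 lower) with the smooth muscle score as a covariate, where edgeR gave 1783 genes an unadjusted p under 0.05. That score separates the diets, so the fit cannot fully tell the score from the diet, and the loss of calls decides nothing. Of 35 lists camera called 17, 0 with an estimated correlation and fry 0. With that covariate 9 were called (6 of them among the 17, of which the enteric neuron list was called in the other direction, up, with adjusted p = 1.65e-06), with the epithelium scaling 12 (11 among the 17) and without casein 1 and chicken 1 17 (12 among them). RLE factors, library size alone and the 1 CPM filter called 17, 13 and 16, all among the 17. The authors' calls were recovered to 37% by edgeR and 100% by DESeq2.

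Whether the shared numbers pair the libraries stays open. The correlations of deviations from the diet means were 0.07, 0.11 and -0.01 for same-numbered pairs. Only casein 2 and chicken 1 correlated best with the library of their own number, and the highest correlation was that of casein 1 with chicken 3 (0.14). However, small-intestine transcripts were high in both libraries numbered 1 (Fabp6 at 128 and 28.6 CPM in casein 1 and chicken 1, and at most 2.26 CPM elsewhere). With the replicate number as a block 567 genes were called (94 higher, 473 lower), and 17 lists, 16 of them among those reported; the sulphide list lost its call (adjusted p = 0.13).

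The sign of Tjp1 turned with library size alone (-0.14). Leaving out 1 library, Tjp1 ran from -0.05115 (without casein 2) to 0.0975 (without casein 3), and Slc15a1 and Reg3g from -7.245 and -9.746 (without chicken 1) to 0.90 and 1.49 (without casein 1). With the epithelium scaling signs turned for Slc16a1 (-0.12), Tjp1 (-0.39), Ocln (-0.24) and the medians of the goblet (-0.0395), oxidative phosphorylation (-0.20), sterol (-0.26), sulphide (-0.11) and short-chain fatty acid (-0.12) lists, as that scaling lowers all values alike. With the smooth muscle covariate they turned for Ret (0.0356), S100b (0.19), Slc26a3 (-0.12), Slc16a1 (-0.0072), Slc15a1 (8.15), Reg3g (11.46) and Ocln (-0.02132). The medians of the adipocyte (0.27), oxidative phosphorylation (-0.04), enteric neuron (0.96) and short-chain fatty acid (-0.0072) lists turned as well. The smooth muscle median (0.014) lay near 0 by construction, because the covariate is the mean of that list. As the covariate also separates the diets, the fit cannot fully tell it from the diet, and the other turns decide nothing. None of the genes whose sign turned was called with all libraries. Of the 65 named genes called, edgeR lost 64 or more without chicken 1, without chicken 2, or without both casein 1 and chicken 1. Depth limits genes of low abundance, where 3 reads correspond to 0.121 to 0.206 CPM.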

Other observations

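Genes and families in this paragraph were chosen after their values were seen. Of 32 tested collagen genes beyond the fixed lists, 15 were called lower on chicken protein and 0 higher (median log2 fold change -1.28, and between -1.24 and -1.71 in the other scalings). Of 10 laminin genes, 6 were called lower and 0 higher (median -1.18, and between -1.14 and -1.6 in the other scalings). Col4a1 and Col4a2, chains of the basement membrane collagen, fell from 486 ± 178 to 124 ± 7.85 CPM and from 374 ± 141 to 62.0 ± 9.38 CPM, and Lamc1, a laminin chain, from 110 ± 13.5 to 19.3 ± 4.16 CPM (SD, n = 3). Tgfbr2, a receptor for the growth factor TGF-beta, fell by 2.01 ± 0.16 on the log2 scale (SE), and Ltbp4, which binds that factor in the matrix, from 374 ± 63.2 to 107 ± 3.20 CPM. Among higher genes, Emp1, a membrane protein of epithelia, rose from 2122 ± 258 to 3851 ± 423 CPM, Aldh1a1, which makes retinoic acid, from 14.5 ± 2.53 to 52.3 ± 12.3 CPM, and Efna1, an ephrin ligand, from 140 ± 17.1 to 291 ± 48.3 CPM. Ribosomal protein genes had 1 call in each direction of 83, with a median of 0.17 that was -0.27 under the epithelium scaling.

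All tests below other than the splits of the libraries were chosen after the results were seen. The 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05. The diets gave 1063 calls, the highest of the other splits 1, and 1 of 10 splits gave as many as the diets. For lists called by camera the diets gave 17 and the highest of the other splits 20, with 5 of 10 splits reaching as many as the diets. The number of lists called at the preset correlation thus does not set the diets apart from other splits.

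Of 30 connective tissue genes 22 and of 29 smooth muscle genes 9 were called lower on chicken protein, while neither list passed with an estimated correlation (adjusted p = 0.596 and 0.646). The epithelium list had a median of 0.43, with 0 of 23 members called and scores that overlapped between the diets. With reads thinned to the smallest library the fibroblast list kept a median log2 fold change of -1.39 (SE 0.122 over members, which co-vary). Equal read totals thus did not remove its fall, though thinning by design changes the fold changes of well-expressed genes little. A larger epithelial share that lowered all other cell types alike would lower the fibroblast and endothelium lists equally. The fibroblast mean log2 fold change minus the endothelium mean was -0.78 (95% interval over members, which co-vary, -1.1 to -0.463). By library, the fibroblast score minus the endothelium score was 2.1 to 2.25 on casein and 1.23 to 1.57 on chicken protein. A share that lowers other cell types unequally was not tested. It stays open whether some pieces of tissue held more muscle wall: within each diet, smooth muscle and enteric neuron scores ordered the libraries alike (6 of 6 pairs; one-sided exact p = 0.0278, the smallest that 36 orders allow), but smooth muscle separated the diets, so a piece with more wall cannot be told apart from an effect of the diet on the wall. With the smooth muscle score as a covariate the fibroblast median was -0.55 and edgeR called no gene (1783 at an unadjusted p under 0.05). As that score separates the diets, this fit cannot fully tell the score from the diet and does not decide between them.

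B cell transcripts were high in casein 2, where Cd79a, the B cell receptor's signalling chain, had 125 CPM and Cr2, a complement receptor of B cells, 241 CPM. A difference between the diets stays open, as the scores overlapped (lowest casein minus highest chicken -0.467). Irf4 separated the diets, but it was named because it was called, and all 1063 called genes did so. The fibroblast score of casein 2 lay 1.01 above the highest chicken library (SD of chicken libraries 0.19), as a casein library's would. A wrong label for casein 2 still stays open, because that score may follow the piece of tissue as well as the diet. A candidate explanation is lymphoid tissue in that sample, because the T and NK cell score of casein 2 also lay 1.35 above the highest other library (SD of the others 0.135), and none of the lists was used to sort samples.

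Small-intestine transcripts were high in casein 1 and next in chicken 1. Fabp6, the ileal bile acid binding protein, had 128, 0.247 and 2.26 CPM in casein 1, 2 and 3 and 28.6, 0.0688 and 0 CPM in chicken 1, 2 and 3, and Anpep, a brush border peptidase, 516 CPM in casein 1 and 63.8 CPM in chicken 1. Of 19 tested list members 14 were highest in casein 1, which restates the pattern, so small-intestinal tissue in that sample stays open. Some list members are expressed in the cecum as well, such as Fabp2, which was not highest in casein 1 (840 ± 179 CPM on casein and 1665 ± 394 CPM on chicken protein). Carry-over of RNA from casein 1 into chicken 1 would keep 1 ratio, but the ratios ran from 2.65% for Reg3g (95% interval 2.31 to 3.02) to 27.2% for Cubn (20.2 to 36.1), a factor of 10.3. Reg3g has paralogs that can share its reads, but Apob (8.05%, 7.04 to 9.16) and Fabp6 (22.4%, 20.4 to 24.7) also lay apart. No biological explanation was tested. Without both libraries, and so with fewer samples in the fit, 5 genes were called. The fibroblast and smooth muscle medians were then -1.07 and -0.932, against -1.35 and -1.22 with all libraries.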
